A study of Homo sapiens with 2 samples.

How the data were processed

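Total RNA of MDA-231 and MDA-231-GEM cells was amplified, labelled with biotin and hybridised to Affymetrix expression arrays read at the 3' end of transcripts, per the labels' protocols. There was 1 array per cell line and nothing was pooled. The deposited values were log2 signals, 1 per probe set and array. MAS5 is named in the submitters' processing notes as the software; its version, target level, detection calls and filters were not given in the sources used here. MAS5 combines the perfect match and mismatch probes of a probe set into a signal and scales each array to a common trimmed mean. The base of the logarithm and the scaling were checked on the values: with base 2, the 2% trimmed mean of the linear signals came to 500.1 on both arrays. The deposited values were used as scaled by the authors. On the MDA-231 array 246 probe sets were listed at 0, and on the MDA-231-GEM array 2 were.

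Each array held 54675 probe sets, of which 62 were controls. Of the other 54613, the platform annotation of 2016 gave 1 gene to 41091, several genes to 1801, and 11721 were unnamed here. Only probe sets with 1 gene were used for genes. Symbols were updated through Entrez identifiers to the RefSeq table of GRCh38.p14, which matched 41037 of these probe sets; the other 54 kept the annotation's symbol. Genome coordinates are not printed, since the array values name no build, and the RefSeq table served only for names, chromosome and gene order. This gave 19775 genes.

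A gene's value was its probe set with the highest mean log2 signal. Probe sets ending in _x_at, which can cross-hybridise, were left out where the gene had another. The floor was the mean of both arrays' median log2 signal (6.30, a linear signal of 79). A gene was measured if it exceeded the floor on at least 1 array. Signals below the floor were set to it, and the fold is then written as at least that size. Genes below the floor on both arrays got no ratio. With 1 array per group no test of a gene is possible, so genes were counted by size: a log2 difference of 1 or more in either direction. The precision of an array value comes from its brightness, and error was estimated as the standard deviation of the log2 difference between measured probe sets of a gene.

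The 42 gene lists hold 733 genes, of which 655 were on the arrays with a probe set of their own and 78 were not used here. The median of a list with at least 5 measured genes was set beside 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list is called above or below where its median lay outside their central 95%. Running medians over 15 neighbouring measured genes were set beside the most extreme windows of 1000 shuffles of the genes over the same positions, repeated under each alternative. Chromosome medians were set beside 1000 random sets matched the same way.

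Genes were named by a rule. It took the 12 largest increases and 12 largest decreases among genes with 2 or more measured probe sets that all differed by 2-fold the same way. It took the 5 largest in each direction among genes with 1 measured probe set whose brighter array was above the 75th percentile. It also took up to 4 members of each list with the largest differences of 2-fold or more, a fixed set of gemcitabine and cell state genes (DCK, SLC29A1, CDA, RRM1, RRM2, ABCB1, ABCG2, CDH1, VIM and CD44) and the members of the extreme windows. A gene named outside the rule is marked as chosen after its value was seen.

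The lists, the floor, the size rule, the naming rule, the windows and most alternatives were chosen before the data were examined. These alternatives were setting the median difference to 0, quantile normalization, floors at the 30th and 70th percentiles, no floor with 16 added to the linear signals, the mean over probe sets, _x_at probe sets allowed, thresholds of 1.5-fold and 4-fold, concordant probe sets only, and windows of 25 genes. Chromosome medians, gene families, a lowess correction over signal (span 0.2, 3 iterations) and lists without the genes of chromosomes X and 13 were added after the data had been seen. No scaling moved the median difference of measured genes, 0.10 as deposited, by over 0.1.

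The procedure was tested on simulated data made from these 2 arrays. The changed genes were drawn from the brighter ones, and noise was set near the spread between probe sets, without spread between cultures. Of 33 genes per fold size and direction, 32 or 33 were called at log2 changes of 1.5, 2 and 3, in a run of 12894 genes. A list shifted by 0.6 came back with a median of 0.62, 1 of 37 unchanged lists lay outside its random range, and a block of 40 neighbouring genes shifted by -1 gave a lowest window of -1.08. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.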

Results

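Gene expression was compared between MDA-231 cells, a human triple-negative breast cancer line with mesenchymal features, and MDA-231-GEM, a gemcitabine-resistant subline derived from it by raising the drug concentration step by step. Gemcitabine is a deoxycytidine analogue that cells phosphorylate and build into DNA, and its diphosphate inhibits ribonucleotide reductase. The comparison asks which genes differ between resistant and sensitive cells, as a lead to how resistance arises. RNA came from cells in logarithmic growth, and the labels list no treatment for either culture. Each cell line was read on 1 Affymetrix expression array with 54675 probe sets, so the number of arrays limits the precision and no difference between the lines has a replicate check. All differences below are log2 signal in MDA-231-GEM minus log2 signal in MDA-231, they describe these 2 arrays, and no p-value is given.

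The 2 arrays had the same trimmed mean signal (500.1 on the linear scale) but not the same distribution. The median log2 signal of gene probe sets was 6.01 in MDA-231 and 6.60 in MDA-231-GEM, while the 75th percentiles were 8.58 and 8.63. Across probe sets, which are not independent replicates, the arrays correlated with a Pearson r of 0.859. The internal error could be read from genes with several probe sets: within 6210 such genes the log2 difference had a standard deviation of 0.49 between probe sets, 0.53 for probe sets with a mean log2 signal below 6.69, 0.60 from there to 8.32, 0.33 from there to 10.14 and 0.22 above. This is an error within the arrays and leaves out the spread between cultures. Signals below the floor were set to it first, which narrows the spread of the dimmest probe sets. The values by signal cover only genes with several probe sets in the same range, so bright and dim probe sets of a gene were not compared there. Spiked hybridisation controls differed by -0.00 (bioB), 0.13 (bioC) and 0.16 (bioD). The brightest of them, cre, was 0.55 higher on the MDA-231-GEM array as deposited and 0.10 lower after quantile normalization (difference -0.10). Poly-A controls differed by -0.21 (dap), -0.18 (lys), 0.02 (phe) and -0.18 (thr) as deposited. The control probe sets of GAPDH differed by 0.80 and those of ACTB by -0.06. Probe sets with a mean log2 signal of 15 to 16 were 0.82 higher in the median (60 probe sets), against -0.10 for those at 10 to 11 (2789 probe sets). The 3'/5' signal ratio of the ACTB control probe sets was 3.82 in MDA-231 and 4.87 in MDA-231-GEM, and that of GAPDH was 1.18 and 1.44.

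Of the genes that handle gemcitabine, CDA, which encodes the cytidine deaminase that inactivates the drug, was 3.22-fold higher in MDA-231-GEM (log2 8.69 against 10.38). DCK, the deoxycytidine kinase that carries out the first phosphorylation, was 1.63-fold lower (11.91 against 11.21). ABCG2, a drug efflux transporter, was 6.15-fold lower (log2 8.38 in MDA-231-GEM). RRM2B, the p53-inducible small subunit of ribonucleotide reductase, was 2.37-fold lower, and SAMHD1, a hydrolase of deoxynucleoside triphosphates, was 2.81-fold lower. RRM1 and RRM2, the main subunits of ribonucleotide reductase, differed by -0.06 and -0.13, and both were among the brighter genes (log2 13.7 and 13.8 in MDA-231). SLC29A1, the main nucleoside importer for the drug, differed by -0.24 with its brightest probe set and by -1.59 with its other one. ABCB1, the P-glycoprotein efflux pump, lay below the signal floor in MDA-231 and just above it in MDA-231-GEM (log2 6.60 against a floor of 6.30), and it passed 2-fold with the floor at the 30th percentile (1.68) and with no floor (2.10).

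As groups, these lists did not stand apart from random lists of genes of like brightness. None of the 7 measured uptake and activation genes differed by 2-fold, with a list median of 0.09. Among 9 inactivation genes, CDA was higher and SAMHD1 lower (median 0.09). Among 10 genes of ribonucleotide reductase and dNTP supply, RRM2B was lower and the median was -0.21. Among 9 efflux transporters, ABCG2 was lower and the median was -0.19, with -0.56, below the random range, when probe sets were averaged. CDA, ABCG2, RRM2B and DCK each rest on 1 measured probe set, and the mean over 3 probe sets put SAMHD1 at -0.82, short of 2-fold.

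**Figure D1:**
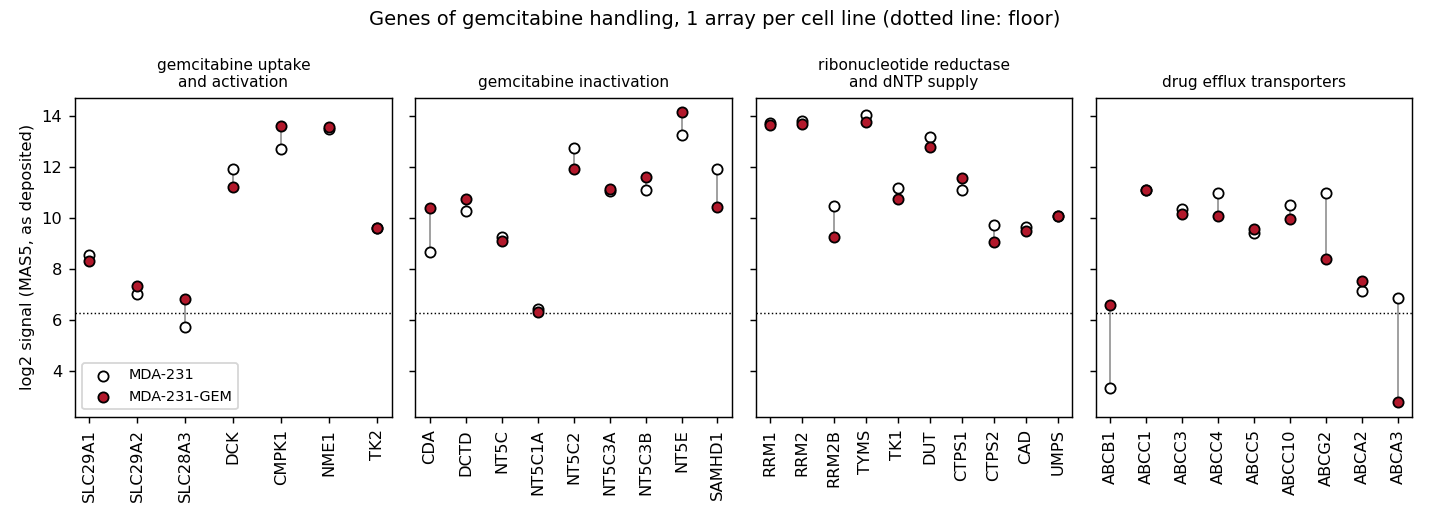
Deposited log2 signal of the measured genes of 4 gemcitabine-related lists in MDA-231 (open circles) and MDA-231-GEM (filled circles), 1 array each, with the signal floor as a dotted line. CDA lies higher in MDA-231-GEM (10.38 against 8.69), ABCG2, SAMHD1 and RRM2B lie lower, and RRM1 and RRM2 nearly coincide.

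Across the transcriptome, 1184 of 13757 measured genes were at least 2-fold higher in MDA-231-GEM and 787 were at least 2-fold lower. For 418 of the higher and 158 of the lower genes the dimmer array lay below the floor, so their fold is a lower bound. At 8-fold or more, 47 genes were higher and 47 lower. Among 6200 genes with several measured probe sets (10 of the 6210 above were left out, since the probe set that stands for the gene lay below the floor on both arrays), 142 were higher and 129 lower with every probe set past 2-fold. In 59.2% of the 6210 genes all measured probe sets differed in the same direction. The brightest measured probe set passed 2-fold in 863 of them, and the mean of the others had the same sign in 87.1% of these. Higher genes made up 60.1% of all 2-fold differences, 51.1% among the genes above the 75th percentile of brightness and 49.6% with the floor at the 70th percentile. The share was 50.4% when the median difference was set to 0 and 50.7% after quantile normalization, settings that bring the 2 directions nearer by construction.

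The largest increases seen with several probe sets were those of FAM133A (at least 30.3-fold), SPARC, a secreted matrix protein (at least 27.3-fold), ADGRF1, an adhesion G protein-coupled receptor (at least 20.3-fold), and KYNU, kynureninase of tryptophan breakdown (19.2-fold, log2 8.41 against 12.68). They were followed by CPPED1 (at least 11.7-fold), RGS4, a regulator of G protein signalling (10.9-fold), ABCG1, a cholesterol exporter (at least 10.8-fold), UGT8, MPZL2, CA12, a carbonic anhydrase (9.33-fold), ADAMTS6 and PTGFRN (8.77-fold). These folds are those of the brightest probe set; the smallest log2 difference was 2.66 for SPARC, 1.64 for ADGRF1, 1.21 for ABCG1, 1.45 for UGT8, 1.29 for MPZL2, 1.36 for ADAMTS6 and 1.33 for PTGFRN. Genes with a single measured probe set included SCG5 (46.4-fold) and SCG2 (24.1-fold), both of the granin family of secretory granules, LRIG1, a negative regulator of ERBB receptors (at least 36.9-fold), CHRDL1, a BMP antagonist (26.6-fold), and L1CAM, a cell adhesion molecule (26.5-fold).

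The largest decreases seen with several probe sets were those of ADAMTS1, a secreted metalloprotease (56.4-fold, log2 12.24 against 6.43), MAN1A1, a Golgi mannosidase (at least 29.5-fold), DCLK1, a doublecortin-like kinase (27.9-fold), CCN3, a matricellular protein (12.7-fold), and CXCR4, the CXCL12 receptor (12.4-fold). FAT3 (at least 12.3-fold), CA13 (log2 difference -3.58), WNT5A, a non-canonical Wnt ligand (10.2-fold), PLEKHA7, an adherens junction protein (9.11-fold), ATOH8, GALNT12 and FST, the activin-binding follistatin (7.22-fold), came next. The smallest log2 difference was -3.82 for ADAMTS1, -1.42 for MAN1A1, -1.45 for DCLK1, -1.12 for CA13, -1.82 for WNT5A, -1.29 for ATOH8 and -1.21 for GALNT12, so the order holds for the brightest probe set alone. Genes with a single measured probe set included TSPAN8, a tetraspanin (113-fold, log2 13.42 against 6.60), GKN2 (at least 59.5-fold), FABP5, a fatty acid binding protein (at least 56.6-fold), GPC6, a glypican (at least 43.5-fold), and GJA1, a gap junction connexin (at least 41.5-fold). In a simulation built on these 2 arrays, a change of 1.5 on the log2 scale was called in 32 or 33 of 33 genes per direction, and 348 of 12641 unchanged genes (2.75%) were called too. The changed genes were drawn from the brighter ones, and noise was set near the spread between probe sets. Spread between cultures and the unequal distributions of the arrays were left out, so these rates do not carry over to the real calls.

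**Figure D2:**
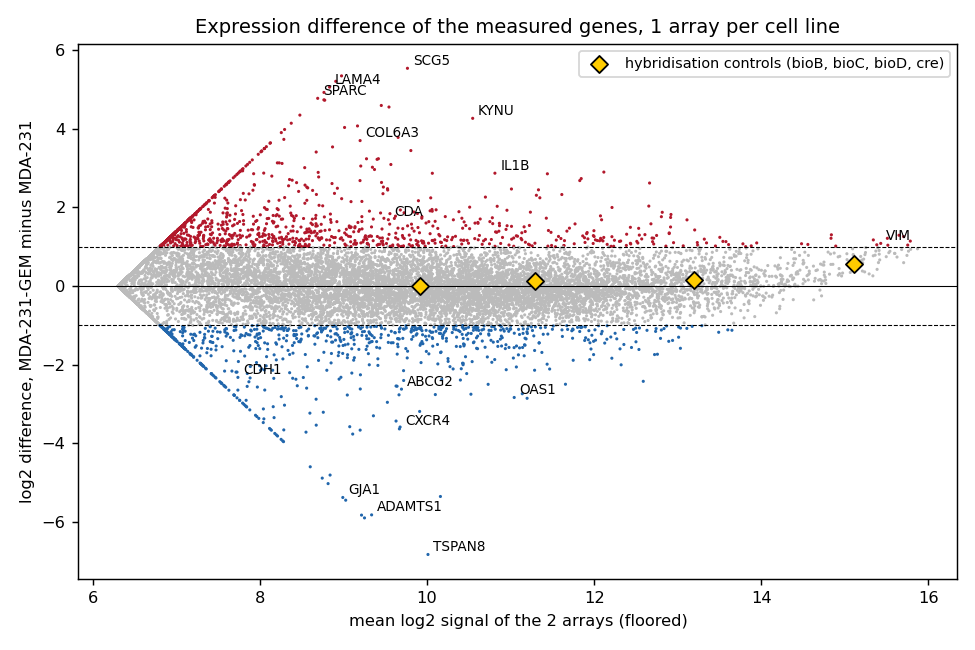
Log2 difference (MDA-231-GEM minus MDA-231) of each measured gene over its mean log2 signal, with values below the floor set to it; red and blue points are at least 2-fold higher or lower, and diamonds are the hybridisation controls. TSPAN8 lies lowest at -6.82 and SCG5 near the top at 5.54, and the cre control sits at 0.55 at the bright end.

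The lists of mesenchymal markers, integrins and laminins, and extracellular proteases had medians above those of matched random lists. Of 42 gene lists fixed before the data were examined, 41 had at least 5 measured genes. Of these, 10 had a median above the central 95% of matched random lists and 2 below it. About 2.05 in all would fall outside if the genes of a list varied independently. The random lists draw genes singly, while genes of a list can move together and some lists share genes (752 entries, 733 genes). The number 2.05 therefore does not measure chance between cultures with 1 array each. Fibroblast and stromal markers, a cell type list, were among the higher ones (median 0.82 over 11 genes). Among 16 mesenchymal markers, 6 were 2-fold higher and 2 lower (median 0.52), with SPARC, COL1A1, the main fibrillar collagen chain (8.29-fold), SNAI2, a repressor of epithelial genes (5.45-fold), and COL5A1 (3.31-fold) leading. TAGLN (-1.43) and LOX (-1.29), chosen after their values were seen, were the 2 lower ones. VIM, the mesenchymal intermediate filament, was 2.12-fold higher, but at log2 14.89 and 15.97 it lies in the bright range where most probe sets were higher, and quantile normalization left 0.27. The mesenchymal list fell inside the random range under quantile normalization (0.18), with a floor at the 30th percentile (0.11), with no floor (0.19) and with shared _x_at probe sets allowed (0.37).

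Among 13 epithelial markers, 2 were higher and 2 lower (median -0.14, inside the random range). CDH1, E-cadherin, was lower (log2 8.90 against 6.57, a difference of -2.32), and OCLN, a tight junction protein, was 2.80-fold lower; CDH1 fell short of 2-fold with the floor at the 70th percentile. CLDN7, a claudin, was 2.90-fold higher and CRB3, a polarity protein, at least 3.18-fold higher. Integrins and laminins were higher as a group (median 0.54 over 18 genes, 3 higher and 1 lower). ITGA2 and ITGA5, collagen and fibronectin receptor chains, were 3.21-fold and 2.88-fold higher, LAMA5 was 2.21-fold lower, and LAMA4 was at least 33.3-fold higher by its brightest probe set and 0.46 on the log2 scale by its other one; ITGA5 fell short of 2-fold with the floor at the 70th percentile. Of 22 extracellular proteases and inhibitors, 7 were higher and 2 lower (median 0.54): CTSL, cathepsin L, was 6.65-fold higher and SERPINE2, a protease inhibitor, 5.53-fold higher, while ADAMTS1 and MMP1, interstitial collagenase (3.96-fold), were lower.

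The TGF-beta response list was higher (median 0.59 over 17 genes, 4 higher and 2 lower). PMEPA1, a TGF-beta target and feedback inhibitor, was 4.80-fold higher, INHBA, the activin A subunit, 4.67-fold higher and TGFB1 2.30-fold higher, while ID3, a target of BMP signalling, was 3.30-fold lower. TGFBI (1.02) and ID1 (-1.01), chosen after their values were seen, just passed 2-fold, and TGFB1 fell short of it after quantile normalization and after a lowess correction over signal. The Wnt and Notch list stayed inside the random range (median 0.41 over 17 genes, 4 higher and 2 lower): WNT5A was lower, LEF1, a Wnt-responsive transcription factor, was 4.15-fold lower by its brightest probe set and 0.09 higher by its other, and HEY1, a Notch target, was 3.29-fold higher, as was WNT5B (2.06-fold). NOTCH1 (1.04) and HEYL (at least 1.01), also chosen after their values were seen, were the other two higher genes. HEY1 fell short of 2-fold with the floor at the 70th percentile, WNT5B with the median difference set to 0 and LEF1 when its probe sets were averaged. Of 13 stem cell and pluripotency markers, 3 were higher and 2 lower (median 0.24, inside the range, but above it with the floor at the 30th percentile, 1.35, and with no floor, 1.06). ALDH1A3, an aldehyde dehydrogenase used to mark breast stem cells, was 3.04-fold higher, KLF4 2.84-fold and CD44, the hyaluronan receptor, 2.11-fold, with its 8 measured probe sets between 0.89 and 1.90; CD44 is also a bright gene (log2 15.02) and was at 0.75 after quantile normalization. LGR5 was at least 14.9-fold lower by its brightest probe set, -0.09 by its other and -0.39 after quantile normalization, and CD24 (-1.02, chosen after its value was seen) was the other lower member.

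The NF-kB target and antigen presentation lists were above the random range. Among 21 NF-kB targets and cytokines, 8 were 2-fold higher and none lower (median 0.69). IL1B, the secreted interleukin, was 7.31-fold higher (log2 9.38 against 12.25), CSF3 at least 5.94-fold, the chemokine CCL5 4.56-fold and IL1A 4.32-fold. Among 17 antigen presentation genes, 5 were higher and none lower (median 0.81). The median was 0.40 after quantile normalization and 0.40 after lowess, above the random range both times. The class II chains HLA-DPA1 and HLA-DRA were 5.72-fold and 5.30-fold higher, CD74, their invariant chain, 3.17-fold (0.06 on the log2 scale by its other probe set), NLRC5, an activator of class I genes, 2.74-fold, and HLA-DMA, chosen after its value was seen, differed by 1.24. CSF3, CCL5 and IL1A fell short of 2-fold with the floor at the 70th percentile, as CD74 did when its probe sets were averaged.

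Interferon-stimulated genes went both ways, with a median of 0.17 and a mean of -0.15 over 24 genes, inside the random range. OAS1 and OAS3, oligoadenylate synthetases that activate RNase L, were 7.12-fold and 5.79-fold lower (OAS3 by -0.38 on the log2 scale with its other probe set), and IFIT2 and IFIT1, inhibitors of viral RNA translation, 3.57-fold and 3.34-fold lower. MX1 (2.83-fold) and XAF1 (2.85-fold), chosen after their values were seen, were the 2 higher members.

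The stress response lists had medians above the random range with the values as deposited, though few of their genes passed 2-fold. The list of the unfolded protein and integrated stress responses had a median of 0.53 over 18 genes, with PHGDH, of serine synthesis (at least 2.53-fold), HSPA5, the main chaperone of the endoplasmic reticulum (2.47-fold), and CALR, calreticulin (2.28-fold), higher and none lower. HSPA5 is bright (log2 15.49) and fell short of 2-fold after quantile normalization (0.85), and CALR was at 0.08 once _x_at probe sets were allowed and short of 2-fold with the floor at the 70th percentile, quantile normalization and lowess. NRF2 targets and glutathione genes had a median of 0.44 over 19 genes: AKR1C3, an aldo-keto reductase, was 8.52-fold higher, HMOX1, heme oxygenase, 2.89-fold higher and ME1, malic enzyme, 2.24-fold lower. This list fell inside the random range after quantile normalization (0.24), with the floor at the 70th percentile (0.22) and after lowess (0.26).

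Cholesterol and fatty acid synthesis genes were lower as a group (median -0.42 over 16 genes, interquartile range -0.59 to -0.20). Only FDPS, farnesyl diphosphate synthase, passed 2-fold (2.06-fold lower), and the list's median of -0.29 with all probe sets averaged lay inside the random range. Hypoxia and glycolysis genes were inside the range (median 0.22 over 21 genes, 5 higher and 1 lower): ADM, adrenomedullin, was 2.39-fold higher, EGLN3, a prolyl hydroxylase, 2.37-fold, NDRG1 2.28-fold, SLC2A3, a glucose transporter, 2.11-fold and PGK1 2.08-fold, and HK2 (-1.01, chosen after its value was seen) was lower. EGLN3 and PGK1 fell short of 2-fold after quantile normalization and lowess, and SLC2A3 and PGK1 with the median difference set to 0 and when probe sets were averaged. None of 18 oxidative phosphorylation genes differed by 2-fold (median -0.02, mean 0.04).

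Mitotic genes were lower as a group by a small amount. The mitosis list had a median of -0.41 over 20 genes, an interquartile range of -0.69 to -0.19 and a percentile of 0.15 among matched random lists, and BUB1, a spindle checkpoint kinase, was its only member past 2-fold (2.16-fold lower). The S phase list was inside the range (median -0.18 over 20 genes), with RFC3, a clamp loader subunit, 2.49-fold lower. Replication checkpoint genes had a median of -0.11 over 15 genes, with CDC25A, a phosphatase that activates cyclin-dependent kinases, 2.14-fold lower and RAD9A, of the checkpoint clamp, 2.11-fold lower. Homologous recombination and Fanconi genes had a median of -0.25 over 13 genes, with FANCM 2.30-fold higher, and excision and mismatch repair genes 0.29 over 17 genes, with XRCC1, a scaffold of base excision repair, 2.16-fold higher. Both lists were inside the range, but excision and mismatch repair lay above it after quantile normalization (0.37), after lowess (0.37) and without the genes of chromosomes X and 13 (0.35). The p53 targets had a median of -0.00 and a mean of 0.09 over 13 genes, with the death receptor TNFRSF10B 2.82-fold higher and TP53INP1 2.54-fold lower. Histones (-0.10 over 13 genes) had no member past 2-fold. DNA and histone methylation enzymes (0.10 over 21 genes) included KDM6A, an H3K27 demethylase (2.37-fold higher), and the DNA methyltransferases DNMT3A (2.19-fold lower, though 0.55 by another probe set) and DNMT3B (2.05-fold lower). The checkpoint, p53, histone and methylation enzyme lists were inside the random range too, but histones lay below it with the floor at the 30th (-0.29) and 70th percentile (-0.49) and after lowess (-0.34). CDC25A and DNMT3A fell short of 2-fold when their probe sets were averaged, RAD9A, FANCM and XRCC1 with the floor at the 70th percentile, XRCC1 also after quantile normalization and lowess, and RAD9A also with no floor.

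Survival and growth signalling lists lay inside the random range, except that anti-apoptotic genes lay above it with the floor at the 70th percentile (0.47) and with _x_at probe sets allowed (0.53). Among 10 anti-apoptotic genes (median 0.33), BCL2A1 was at least 6.05-fold higher and XIAP, an inhibitor of caspases, 2.22-fold higher, and none was lower. Among 15 pro-apoptotic genes (median 0.11), BIK was at least 4.90-fold higher and APAF1, the apoptosome scaffold, 2.66-fold lower. In the PI3K and AKT pathway (median 0.20 over 18 genes), IGF1R was 2.55-fold lower by its brightest probe set, with another at 0.31, and RICTOR, a subunit of an mTOR complex, was 2.23-fold higher. In the EGFR and MAPK output list (median -0.03 over 19 genes), ERBB3, a receptor kinase, was 3.11-fold lower and SPRY1, a feedback inhibitor, 2.27-fold lower, while the EGFR ligands HBEGF and EREG were 2.87-fold and 2.16-fold higher; DUSP6 (-1.08), chosen after its value was seen, was the remaining lower member. Immediate early genes had a median of 0.11 over 12 genes, with DUSP1 2.27-fold lower and IER2 (log2 11.04 against 12.04) and EGR3 (at least 2.02-fold) at the threshold. XIAP, APAF1, IGF1R, ERBB3, SPRY1 and DUSP1 fell short of 2-fold when their probe sets were averaged, and BCL2A1 and BIK with the floor at the 70th percentile. IER2 and EGR3 fell short with the median difference set to 0, IER2 also with no floor and EGR3 also after quantile normalization.

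The marker lists of cell types held both dim and bright genes. KRT18 of the luminal list, chosen after its value was seen, had a log2 signal of 14.19 in MDA-231. Fibroblast and stromal markers had a median of 0.82 over 11 genes, above the random range (1.74 with the floor at the 30th percentile and 1.89 with no floor), with 4 higher: COL6A3, a collagen chain (log2 7.35 against 11.05, a difference of 3.70), FBLN1 (3.51-fold, 0.21 on the log2 scale by its other probe set), LUM (at least 3.21-fold) and PI16 (at least 2.61-fold). FBLN1, LUM and PI16 did not exceed log2 8.14 in MDA-231-GEM. Leukocyte markers had a median of 0.68 over 9 genes, inside the range, with CD14 (at least 3.01-fold) and IKZF1 (2.87-fold) higher. Endothelial markers had a median of 0.19 over 7 genes, with EGFL7 at least 2.31-fold higher (short of 2-fold after quantile normalization). Melanocyte markers had a median of 0.09 and a mean of -0.03 over 5 genes. Neural markers had 4 measured genes, with MBP 2.37-fold lower. Luminal markers had a median of 0.10 and a mean of -0.05 over 12 genes: TFF3, a trefoil factor, was at least 4.12-fold lower and GATA3, a luminal transcription factor, 2.24-fold higher. Basal markers had a median of 0.21 over 6 genes, with MME at least 3.24-fold higher. Cancer-testis antigens had a median of 0.44 over 6 genes and none past 2-fold. TFF3, MME and FBLN1 fell short of 2-fold with the floor at the 70th percentile, and IKZF1 and MBP when their probe sets were averaged. The endothelial, melanocyte, luminal, basal and cancer-testis lists were inside the random range, but the endothelial list lay above it with the floor at the 30th percentile (1.31).

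Ribosomal protein genes had a median of 0.65 over 17 genes, with RPS4X (2.26-fold) and RPS19 (2.06-fold) highest. Both are among the brightest genes of the arrays (log2 15.93 and 16.27 in MDA-231-GEM), and the list's median was 0.039 after quantile normalization, inside the random range. RPS4X and RPS19 fell short of 2-fold after quantile normalization and lowess, and RPS19 also with the median difference set to 0. Reference genes had a median of 0.18 over 12 genes, inside the range, with only PGK1 past 2-fold.

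**Figure D3:**
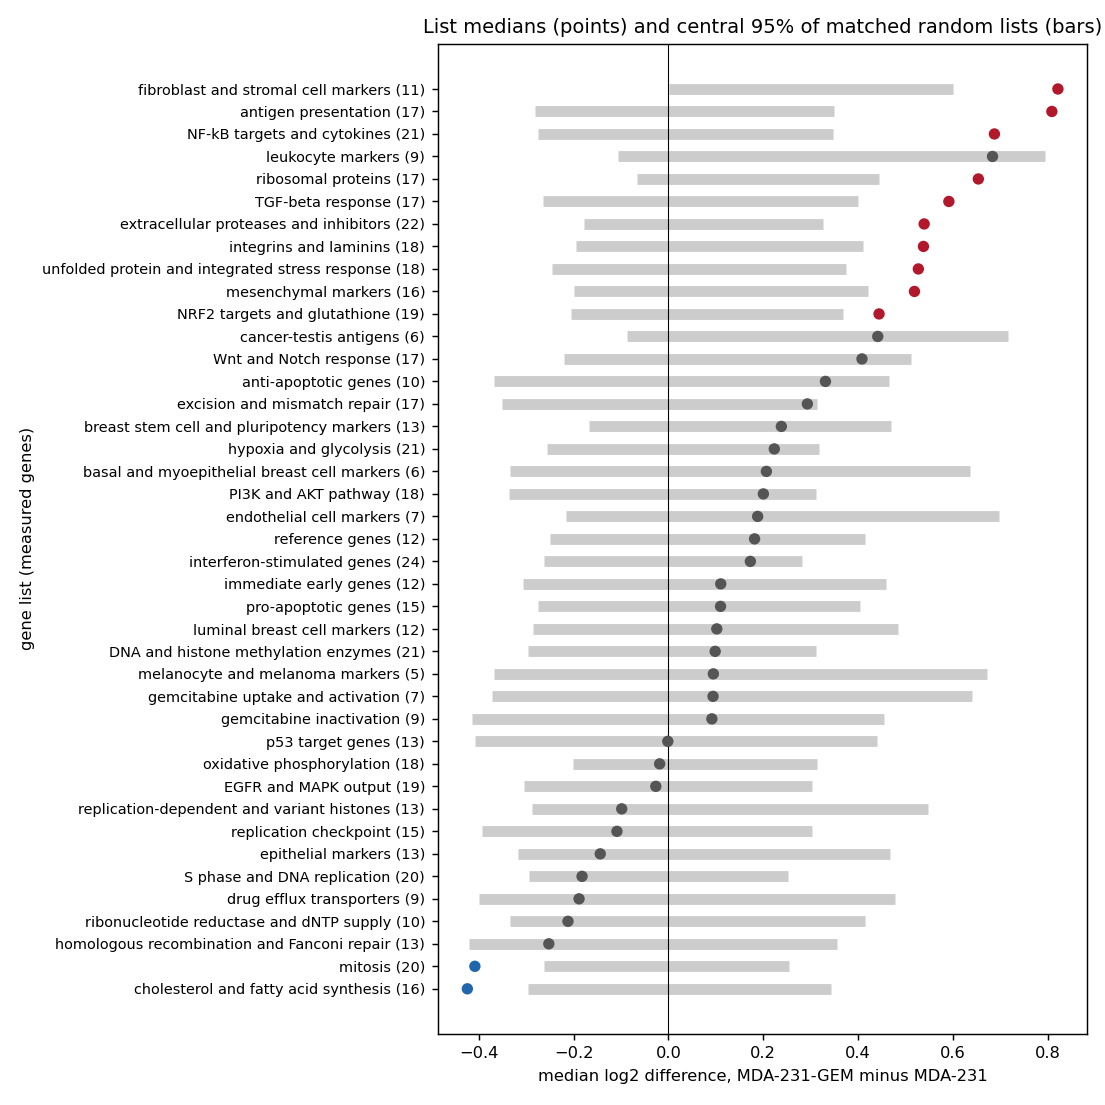
Median log2 difference of each gene list (points, with the number of measured genes) and the central 95% of the medians of 10000 random lists matched on signal (bars). Red points lie above and blue points below their bar, from fibroblast and stromal markers at 0.82 to cholesterol and fatty acid synthesis at -0.42.

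Some stretches of neighbouring genes differed together. Gene order was taken from the RefSeq annotation of GRCh38.p14, which placed 13720 measured genes. The lowest window of 15 neighbouring genes lay on chromosome 13, from FREM2 to NAA16: 14 of its 15 genes were lower, 10 of them at least 2-fold, and its median was -1.33, beyond the most extreme window in 1000 shuffles of the genes (-1.08). MRPS31 (3.89-fold), PROSER1 (3.55-fold), SLC25A15, a mitochondrial ornithine carrier (2.90-fold), KBTBD6 (2.88-fold), NAA16 (2.87-fold), ELF1 (2.81-fold), COG6 (2.69-fold) and FOXO1, a forkhead transcription factor (2.48-fold), were among the lower genes, and LINC00598 (1.01, a bound) was the only higher one. Overlapping windows beyond the shuffles covered 41 genes of chromosome 13 (median -1.15, 36 lower), DCLK1 and RFC3 among them, and 16 genes near the end of chromosome 18 up to NFATC1 (median -1.06, 12 lower), MBP among them. The highest window lay on chromosome X from HDAC8 to TAF9B, with all 15 genes higher. Its median of 1.20 lay above the median highest window of the shuffles (0.85) and below their most extreme window (1.39). This window from HDAC8 to TAF9B held MAGEE1 (at least 7.57-fold), ATRX, a chromatin remodeller (3.40-fold), TAF9B (3.30-fold), PHKA1 (1.59 on the log2 scale), MAGT1 (2.29-fold) and PGK1. Other windows of chromosome X were highest and passed their shuffles with 25 genes (from TBC1D8B, 1.16), after quantile normalization (from TIMM8A, 1.25) and with the floor at the 70th percentile (from PRDX4, 1.31). With no floor the lowest window (-1.31) did not pass its shuffles (-1.38), and the highest window then lay on chromosome 5. NAA16 and TAF9B fell short of 2-fold when their probe sets were averaged, and LINC00598 with the median difference set to 0 and after quantile normalization.

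Chromosome medians differed as well, in a comparison added after the windows had been seen. The 449 measured genes of chromosome X had a median of 0.67 (random sets of the same brightness 0.05 to 0.16), with 122 at least 2-fold higher and 9 lower, and held 10.3% of all higher genes against 3.26% of measured genes. FAM133A, CHRDL1, L1CAM, XIAP, KDM6A and RPS4X are X-linked. The 253 genes of chromosome 13 had a median of -0.62 (random sets -0.02 to 0.14), with 71 lower and 10 higher, and held 9.02% of all lower genes against 1.84% of measured genes. GPC6 and DCLK1 lie there. Smaller shifts were seen for chromosome 9 (median 0.34 over 553 genes), chromosome 10 (-0.23 over 550) and chromosome 18 (-0.15 over 208), and in all 6 of 23 chromosomes lay above and 7 below their random range. Not all of these calls were stable. Chromosomes 17 and 20 fell inside after quantile normalization, with the floor at the 70th percentile and with no floor. Chromosome 17 also did with probe sets averaged, and chromosome 20 with the floor at the 30th percentile and after lowess. Chromosomes 4 and 14 fell inside with probe sets averaged, and chromosome 12 with the floor at the 30th percentile. Chromosome 16 newly lay below with that floor and with probe sets averaged. Chromosome 5 newly lay above with the median difference set to 0 and with _x_at probe sets allowed. With the floor at the 70th percentile chromosome 1 newly lay above.

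**Figure D4:**
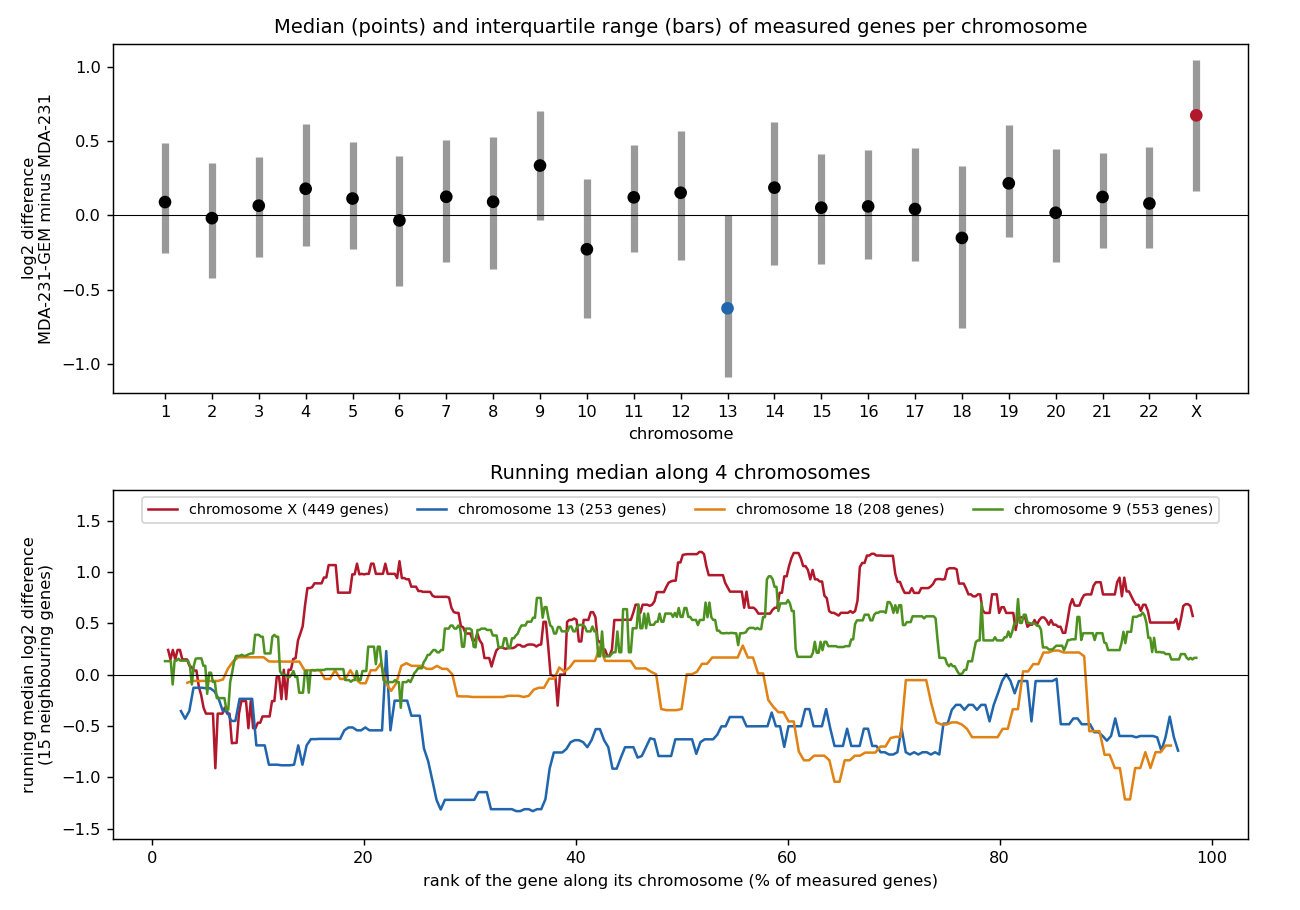
Upper panel: median (points) and interquartile range (bars) of the log2 difference of the measured genes of each chromosome; lower panel: running median over 15 neighbouring genes along chromosomes X, 13, 18 and 9, by rank of the gene. Chromosome X has a median of 0.67 and chromosome 13 of -0.62, and the line of chromosome 13 reaches -1.33.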

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

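All tests of explanations in this part were chosen after the result they bear on had been seen. Control probe sets and unnamed probe sets lie outside the gene comparisons, and 3 signals appeared there. The Alu repeat control probe set, which picks up transcripts that hold these repeats, was 1.405 higher on the log2 scale in MDA-231-GEM (log2 15.37 against 16.77). It was 1.31 higher with the median difference set to 0, 0.66 after lowess and 0.24 after quantile normalization. It lay at the top of the signals of both arrays, which quantile normalization brings together by construction. The 28S ribosomal RNA control probe sets were 0.92 higher (log2 8.97 against 9.89), with 0.82 to 0.95 under the other scalings. Of 5018 measured probe sets that are unnamed here, 500 were at least 2-fold higher (9.96%) and 128 lower (2.55%), a median of 0.29. Among measured genes the shares were 8.61% and 5.72%, so the share of higher ones was close to that of genes. The unnamed probe sets were not matched to genes on brightness.

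Genes of chromosome X were higher in MDA-231-GEM (median 0.67) and those of chromosome 13 lower (median -0.62), a pattern of shifts over most of a chromosome. A trend between the arrays over signal is argued against, since the medians were 0.62 (0.6237) and -0.62 (-0.6161) after a lowess correction, and so are shared probe sets for chromosome X, where plain _at probe sets gave 0.68 (0.6787). Loss of silencing of an inactive X stays open, since the values go both ways: 10 genes known to be expressed from both copies had a median of 0.82 (9 without RPS4X, also 0.82) against 0.72 for the other X genes outside the distal short arm, which speaks against it, while the 90 genes of the distal short arm, a region rich in such genes, had a median of 0.15 (interquartile range -0.40 to 0.85), which goes with it. That region was uneven, with a median of 0.041 from PLCXD1 to CLTRN and of 0.47 from CA5BP1 to DYNLT3. Of the genes 78.8% on chromosome X lay above and 78.7% on chromosome 13 below the median of the other chromosomes, which is consistent with a changed dose of most of each, as a hypothesis, although any cause that acts on a whole chromosome would give such shares. No copy number was measured, and whether the cultures share 1 clonal origin and whether the shifts are linked to gemcitabine selection stay untested.

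Ribosomal protein genes were higher in MDA-231-GEM, with a median of 0.65 (interquartile range 0.42 to 0.77, random lists -0.07 to 0.44). With the lowess correction the median fell to 0.13 (0.02 to 0.26), inside the range of random lists (-0.26 to 0.23), and the call ended because the correction lowered the bright signals where most of these genes lie, so the trend between the arrays over signal could account for that list. A difference between the cultures in these transcripts was not tested apart from the scaling.

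More genes were 2-fold higher than lower. Higher genes made up 49.6% of 2-fold differences with the floor at the 70th percentile against 60.1% with the floor at the median, so dim signals near the floor may account for the surplus. An even offset between the arrays was not separated from this: setting the median difference to 0 gave 50.4%. A difference between the cultures in dim transcripts was not tested apart from the scaling.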

How the results depend on the processing

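The lowess correction and the lists without chromosomes X and 13 were chosen after the data had been seen; the other settings were planned. With 1 array per cell line no array could be left out and no other split exists. No paired analysis was possible because each group has 1 array. No result changed sign past its threshold. Against 1184 higher and 787 lower genes, the counts were 2995 and 1943 at 1.5-fold, 160 and 141 at 4-fold, 142 and 129 with concordant probe sets only, 3220 and 1287 with the floor at the 30th percentile, 506 and 515 at the 70th, and 3379 and 1701 with no floor; the share of higher genes was 71.4% at the 30th percentile and 49.6% at the 70th. Fewer or more dim genes enter by construction, and setting the median difference to 0 (50.4%) or quantile normalization (50.7%) brings the directions nearer by construction. The standard deviation between probe sets was 0.33 at the 70th percentile. The highest window passed its shuffles with 25 genes (1.16), quantile normalization (1.25) and the 70th percentile (1.31), each time another window of chromosome X than in the main result, and the lowest did not with no floor (-1.31). Lists that fell inside the random range were mesenchymal markers with quantile normalization (0.18), the 30th percentile (0.11), no floor (0.19) and _x_at allowed (0.37), NRF2 targets with quantile normalization (0.24), the 70th percentile (0.22) and lowess (0.26), ribosomal proteins with quantile normalization (0.039) and lowess (0.13), and cholesterol and fatty acid synthesis with the mean over probe sets (-0.29). The causes were not tested, except for ribosomal proteins and dim signals. The 12 lists outside the range kept their side in 97 results and lost it in 10, and among the other lists 242 results stayed inside the range and 12 newly left it: excision and mismatch repair with quantile normalization (0.37), lowess (0.37) and without chromosomes X and 13 (0.35), histones at the 30th (-0.29) and 70th percentile (-0.49) and with lowess (-0.34), stem cell markers at the 30th (1.35) and with no floor (1.06), anti-apoptotic genes at the 70th (0.47) and with _x_at allowed (0.53), endothelial markers at the 30th (1.31) and drug efflux transporters with the mean over probe sets (-0.56). Fibroblast markers had too few genes at the 70th percentile. For 159 named genes, 1183 results kept their side of 2-fold, 68 fell short and 6 newly passed. The medians of chromosomes X (0.59 to 0.80) and 13 (-0.72 to -0.35) stayed outside their random ranges. Signal over the floor limits what can be measured.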

Other observations

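All results in this part were chosen after the data had been seen, and genes named here for the first time were picked by their values. Of 30 measured collagens, 11 were 2-fold higher and 2 lower, with a median of 0.67, above the random range and positive under each scaling (0.47 to 0.67). Without the 4 chains of the fixed lists the other 26 had 8 higher and 2 lower and a median of 0.43, inside the random range (-0.05 to 0.46). COL4A5, a basement membrane chain encoded on the X chromosome, was at least 17.6-fold higher, COL7A1, of anchoring fibrils, 7.41-fold and COL6A1, a partner of COL6A3, 7.30-fold, while COL12A1 (-2.50) and COL4A4 (-2.32) were lower. HLA class II genes had a median of 1.64 over 8 genes, 6 of them higher and none lower. This family was picked after HLA-DRA, HLA-DPA1 and HLA-DMA had been seen; the other 5 had a median of 1.005, above the random range (-0.55 to 0.88), with 3 higher. HLA-DRB1 (5.03-fold) and HLA-DPB1 (4.12-fold) stood beside HLA-DRA and HLA-DPA1. Semaphorins, secreted and membrane guidance proteins, had a median of 0.55 over 10 genes, with SEMA3A (5.12-fold), SEMA4D (3.92-fold), SEMA3F (2.75-fold) and SEMA3C (2.32-fold) higher.

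The BEX, TCEAL, ARMCX and GPRASP genes, a cluster on the X chromosome, had a median of 1.06 over 17 genes, with 10 higher and none lower. BEX2 was 6.46-fold higher, TCEAL8 6.21-fold and ARMCX2 5.73-fold. Zinc finger genes named ZNF had a median of 0.35 over 374 genes, 47 higher and 5 lower, and stayed positive under each scaling (0.22 to 0.35). Of these, 174 lie on chromosome 19 (median 0.43), whose own median of 0.22 was above its random range, and the 200 elsewhere had a median of 0.28, above the random range too. The other 13 of 18 families lay inside the random range, among them 13 CXC and CC chemokines (0.37, 4 higher and CCL26 at -1.34), 72 mitochondrial ribosomal proteins (-0.10), 10 tubulins (-0.13), 33 proteasome subunits (0.23) and 59 heat shock and DNAJ proteins (0.15). The activin pair moved apart, with INHBA 4.67-fold higher and FST, which binds activin, 7.22-fold lower.

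Chromosomes X, 13, 8, 9, 10 and 18 were also divided into 10 stretches of about as many measured genes each. On chromosome X the 45 genes at the start, from PLCXD1 to CLTRN, had a median of 0.041, and the other stretches lay between 0.26 and 1.05. On chromosome 13 all 10 stretches were negative, from -0.91 to -0.20. Chromosome 8, whose median of 0.09 lay inside its random range, held a stretch from PTK2B to PLEKHA2 at 0.68, with 96% of its genes positive, and 2 others at -0.42 (HNF4G to GEM) and -0.41 (RAD54B to OXR1). The stretches lay between 0.039 and 0.52 on chromosome 9, between -0.50 and 0.20 on chromosome 10 and between -0.79 and 0.14 on chromosome 18.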
